A study of Streptomyces coelicolor A3(2) with 4 samples.

How the data were processed

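Total RNA of 3 wild-type and 2 pfkA2 mutant extracts of Streptomyces coelicolor was labelled with Cy3 or Cy5 and hybridised in pairs on 4 arrays, per the labels. The arrays held 48 blocks of 19 by 20 spots, and most genes had 1 probe spotted at 2 places. Intensity values are spot amplitudes per dye that the authors obtained with BlueFuse for Microarrays 3.2, per the file headers. How the software treated the background of these amplitudes is not given in the sources used here, and no background columns were used. The fraction columns hold the software's probability of signal per channel and its confidence per spot, per the file headers, and the confidence sets the flags A (above 0.3) and E (below 0.1). The deposited table of processed values holds log2 ratios of mutant over wild type per spot. Its direction, scale and lack of centring were found by comparison with the scanner values, from which it differed by at most 0.0055, and its column medians were 0.38, -0.12, 0.68 and 0.08 for replicates 1 to 4. None of its scale, centring and direction therefore stayed unknown.

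Amplitudes were taken as given, since the files hold no background values, and normexp was not applied. Each array was normalised by loess over all spots with limma 3.58.1 in R 4.3.3, where only chromosomal spots without flag E carried weight. Ratios were turned to mutant over wild type on every array, spots with flag E were left out, and the spots of a gene were averaged. Of 7727 gene names on the array 7455 matched an old locus tag in the annotation of assembly ASM20383v1, and 912 had a symbol there. That annotation served for names and gene order only, because the build behind the array design is not named in the files. Genes with a usable value on all 4 arrays were tested, 7103 in number, and 624 were left out. For the 1 gene name with more than 1 probe all its spots were averaged. Control spots and probes for SCP1 genes stayed out of the test, and 264 SCP1 probes were fitted together with the genes in a separate joint fit for comparison.

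The log2 ratios were fitted with limma (lmFit and eBayes) with a term for the strain and a term for dye orientation. Arrays that share an extract were given 1 common correlation, estimated by restricted likelihood over all genes and held between 0 and 0.5, and the estimate was 0.0278. The fit had 2 residual and 4.42 prior degrees of freedom, the median SE was 0.16, and the median 95% interval reached 0.39 to either side. P-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. The 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera takes its p from the 2 residual degrees of freedom of the fit, unlike with the preset one. Only very large shifts can pass there, so a call lost in that version does not show that a list is unchanged. The percentile of a list median was taken among 10000 random lists matched in 20 bins of amplitude. All arrays were quantified on the same day, so no batch was tested.

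The lists, the design, the settings to be varied and the rule for named genes were fixed before the data were examined. The rule named pfkA2 and its 5 neighbours on either side, the 12 higher and 12 lower genes that passed, filled up by the smallest p where fewer passed, with the same direction on all arrays, and up to 4 members of each list with the largest absolute ratio, together with the cluster regulators and the genes pfkA1, pfkA3 and zwf. SCO4995, SCO7657, SCO3041 and the genes of the scanned windows (SCO0197, SCO0198, adhP, SCO0203, SCO0204, pflA, ppdK, SCO4671, SCO4675, SCO4679, gdhA, SCO4686, SCO4687 and SCO4689) were named after their values were seen. Not every gene that the rule names per list is printed.

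The fit was tested on simulated data in 10 runs of 7103 genes with 200 of them changed. At the estimated correlation of 0.0278 it recovered 67.7% of 2-fold and 98.4% of 4-fold changes, with 10.3 false calls per run, and at a correlation of 0.3 it recovered 35.9% and 95.9%. A list shifted by -0.20 was called by camera with the preset correlation in 7 and in 6 of 10 runs. Camera with an estimated correlation between genes was not run on simulated data. The changes were added in full to the log2 ratios, with errors independent between genes, so signal without a target was not simulated. Each simulated gene had the same variance and dye effect on all 4 arrays. On the real arrays the SD over genes differed, from 0.38 on replicate 3 to 0.75 on replicate 2. The shares recovered therefore hold for ratios with such simulated errors, and they may be too high for these arrays and for transcripts. At the estimated correlation 5.19% of the unchanged simulated genes had an unadjusted p under 0.05 by limma, against 2.62% of genes in the data. The alternatives covered normalisation by block or by the median alone, filters on dim and doubtful spots, the dye term, the correlation between arrays, the deposited ratios, the averaging of spots, the set test, thresholds and leaving out each array. Added after the data were seen were an offset of 50, flag A spots alone, a filter at the 95th percentile of SCP1 probes, array quality weights, camera with an estimated correlation under other normalisations and the scan of gene windows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.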

Results

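Transcript levels were compared between Streptomyces coelicolor M145, a prototrophic laboratory strain without the plasmids SCP1 and SCP2, and a derivative in which an apramycin resistance cassette takes the place of pfkA2 (SCO5426). The gene pfkA2 encodes a phosphofructokinase, the enzyme that commits fructose 6-phosphate to glycolysis, and the series title names overproduction of antibiotics after its deletion. Total RNA from fermentor cultures was used as 3 wild-type and 2 mutant extracts, hybridised in pairs on 4 oligonucleotide arrays of 2 colours. Replicates 1 and 3 carried the RNA labelled mutant in Cy3, and replicates 2 and 4 carried it in Cy5. Replicates 1 and 4 shared mutant extract 1, replicates 2 and 3 shared mutant extract 2, and replicates 3 and 4 shared wild-type extract 2. The labels do not say whether the extracts came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Each array held 18240 spots, 15456 of them for chromosomal genes, and 7103 genes gave a usable value on all 4 arrays. The scanning software gave its best confidence class to 70.5%, 62.0%, 73.0% and 71.7% of the spots on replicates 1 to 4.

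Probes for SCP1 genes, whose target both strains lack, recorded the signal that arises without a target. In the channel labelled wild type the median chromosomal probe was 1.53, 1.22, 1.38 and 1.27 times the median SCP1 probe on replicates 1 to 4, and in the channel labelled mutant it was 1.34, 1.19, 1.23 and 1.27 times. By mean amplitude 975 of the 7103 genes (13.7%) lay above the 95th percentile of SCP1 probes. The SD of the log2 ratios over genes was 0.50, 0.75, 0.38 and 0.41 on replicates 1 to 4, and the number of arrays limits the precision of every value below. Across genes, which are not independent replicates, log2 ratios of mutant over wild type correlated at 0.51 and 0.30 between arrays of the same dye orientation, and between -0.49 and -0.33 for the 4 pairs of opposite orientation. The probe for SCO4995 was the single one whose dye term passed in limma with Benjamini-Hochberg adjustment (adjusted p = 0.0265), with a dye effect of 2.93 on the log2 scale and a log2 ratio of mutant over wild type of -0.023 ± 0.21 (SE). At an unadjusted p under 0.05 the dye term counted 1749 genes.

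**Figure D1:**
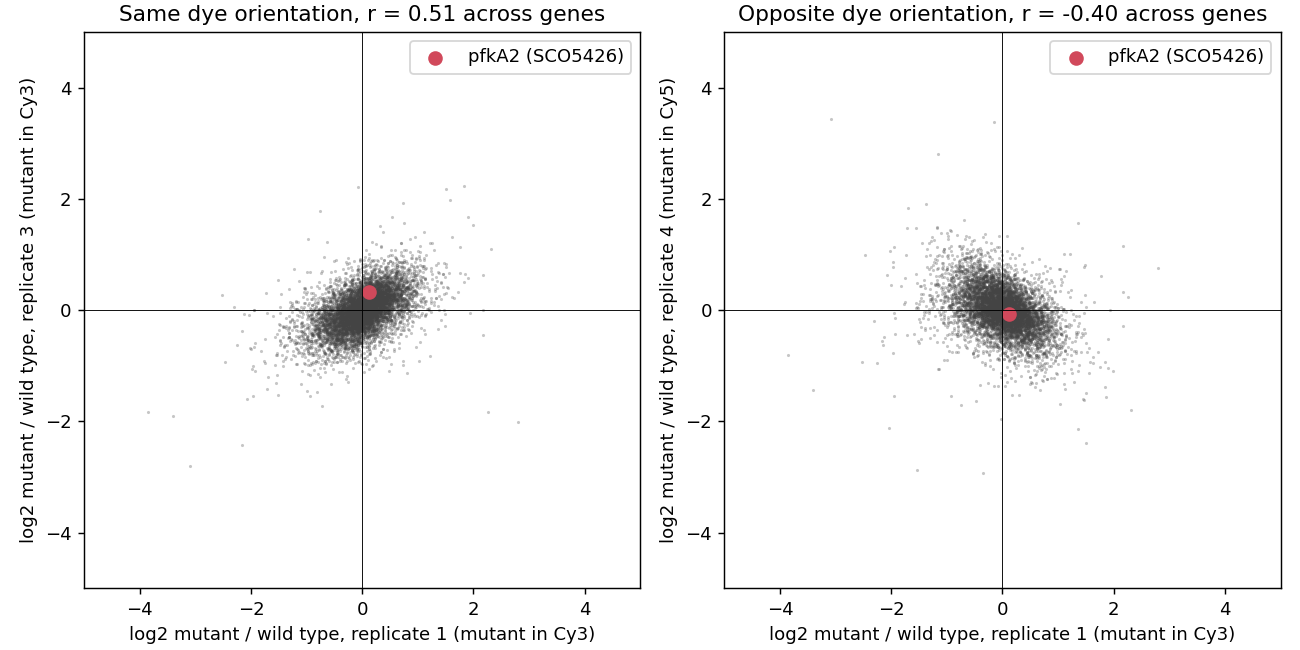
Log2 ratios of the RNA labelled mutant over wild type for 7103 genes (grey points), replicate 1 on the horizontal axis against replicate 3 (same dye orientation, left) and replicate 4 (opposite orientation, right), with pfkA2 in red. The correlation across genes was 0.51 on the left and -0.40 on the right.

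The targeted gene pfkA2 was read first, since it checks the labels. Its log2 ratio of mutant over wild type was -0.11 ± 0.17 (limma estimate ± SE, 4 arrays, 95% interval -0.52 to 0.31), with 0.12, -0.77, 0.32 and -0.071 on replicates 1 to 4. It did not pass the test (limma with Benjamini-Hochberg adjustment, adjusted p = 0.999), and the estimate was 0.073 without replicate 2 and 0.013 with spots of the best confidence class alone. A single probe, spotted at 2 places, stood for the gene, and its position relative to the replaced part is not given in the sources used here. The amplitude of that probe with the RNA labelled wild type was 511, 1243, 2464 and 1966 on the 4 arrays, against 95th percentiles of SCP1 probes of 1809, 5936, 7643 and 8398. The measured pfkA2 signal therefore did not separate the strains, and the samples are called the RNA labelled mutant and the RNA labelled wild type. Ratios of mutant over wild type and the names of extracts follow those labels too. Every direction below rests on the labels and on the file headers, which name the same strain for each dye.

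Of the 10 genes around pfkA2, SCO5424, known as an acetate kinase gene, had the largest ratio, 0.63 ± 0.16 in the RNA labelled mutant, and it was higher on 4 of 4 arrays. Its partner in acetate metabolism, the phosphotransacetylase gene pta (SCO5425), was at -0.062 ± 0.14, and the pyruvate kinase gene pyk (SCO5423) at 0.17 ± 0.17. On the other side of pfkA2, SCO5427 was at 0.051 ± 0.14, SCO5428 at -0.021 ± 0.19 and SCO5430 at 0.012 ± 0.16. SCO5422 (-0.080 ± 0.16) and SCO5429 (-0.0016 ± 0.14) lay near 0 too, with 1 array left out the sign of each neighbour but SCO5424 turned (SCO5423 to -0.0043 and SCO5428 to 0.21 without replicate 2), and SCO5421 and SCO5431 had no usable value on all arrays. By limma 0 of the 9 tested members, pfkA2 included, passed over all genes or when adjusted over the list alone, and SCO5424 had an unadjusted p under 0.05. As a list they had a median of -0.0016, while their mean of 0.066 and the direction of the camera test were positive (adjusted p = 0.462).

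Among genes with ratios below 0, the smallest p belonged to pglX (SCO6627), a methyltransferase gene of the phage growth limitation system, and to SCO0206. In the RNA labelled mutant pglX was at -1.47 ± 0.14 and SCO0206 at -1.50 ± 0.17, and both were lower on 4 of 4 arrays. The same direction on all arrays was a condition for naming the genes of this group, so it is no support for them. On replicates 1 to 4 pglX read -2.15, -0.66, -2.42 and -0.63. Neither passed limma's test with Benjamini-Hochberg adjustment (adjusted p = 0.221 for pglX and 0.321 for SCO0206), and no other gene came closer. SCO0168 (-1.79 ± 0.32), SCO0220 (-1.50 ± 0.34), SCO2866 (-1.48 ± 0.32) and SCO0177 (-1.03 ± 0.20) were also lower on 4 of 4 arrays without passing. The remaining genes of this direction, again lower on every array and short of the threshold, were SCO2868 (-0.85 ± 0.22), SCO1368 (-0.76 ± 0.14), SCO4561 (-0.75 ± 0.17), the aldehyde dehydrogenase gene exaC (SCO1174, -0.66 ± 0.17), SCO0999 (-0.64 ± 0.14) and SCO1186 (-0.55 ± 0.14). Without replicate 4 SCO0220 was at -0.997, and SCO1186 was at -0.24 with loess by block and -0.28 with median centring. SCO4561 lies next to the genes of NADH dehydrogenase.

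In the other direction SCO4678 had the smallest p, with 1.21 ± 0.19 in the RNA labelled mutant. SCO0600, which encodes the osmotic stress sigma factor SigB, was at 1.15 ± 0.33, and SCO3323, which encodes the sigma factor BldN of aerial mycelium formation, was at 0.88 ± 0.26. SCO0417 was at 0.86 ± 0.26, SCO6308 at 0.62 ± 0.19, SCO4680 at 0.60 ± 0.18 and SCO4108 at 0.57 ± 0.14. SCO1001 (0.55 ± 0.17), SCO1276 (0.50 ± 0.14) and SCO4746 (0.49 ± 0.14) completed the group with SCO5424 and the probe of the ribosomal protein gene rplO (SCO4721, 0.57 ± 0.16). All 12 were higher on 4 of 4 arrays, as the rule for naming them required, and none passed (limma, adjusted p = 0.999 for each). Single arrays weighed on some sizes: SCO0600 was at 0.70 and SCO3323 at 0.58 without replicate 2, and SCO0417 was at 0.49 and SCO6308 at 0.40 without replicate 1. With loess by block SCO1276 was at 0.25. The amplitude of the rplO probe with the RNA labelled wild type was 71.9, 528, 191 and 210 on replicates 1 to 4, against medians of 106, 470, 260 and 419 for negative controls. With the RNA labelled mutant it was 189, 542, 667 and 349 against 202, 577, 725 and 291. The rplO probe thus lay at background on most channels, and its ratio is not a measurement of the transcript.

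**Figure D2:**
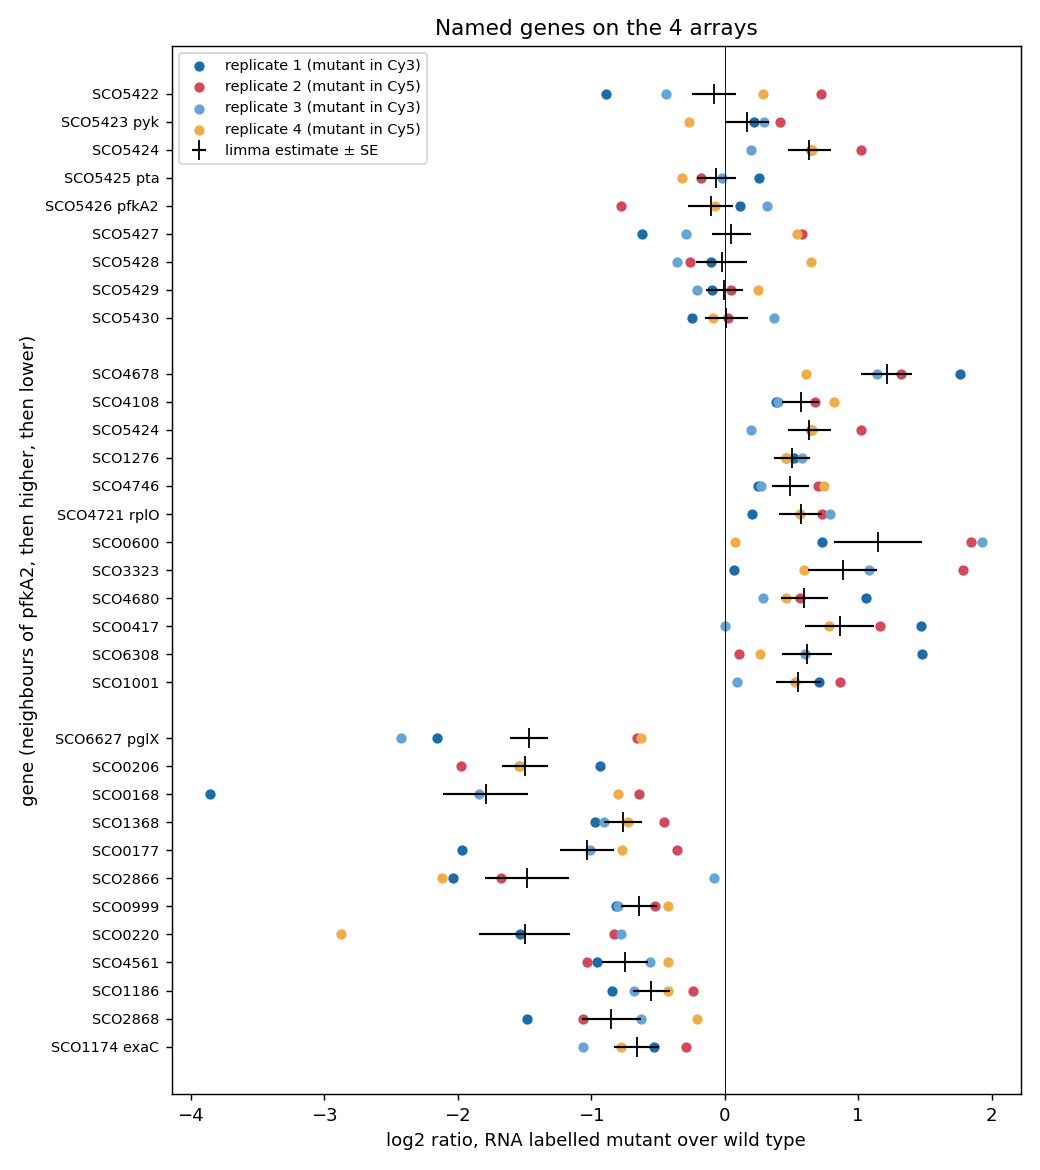
Log2 ratio of the RNA labelled mutant over wild type (horizontal axis) for the tested neighbours of pfkA2, the 12 higher and the 12 lower genes with the smallest p and 1 direction on all arrays. Points are the 4 arrays and black crosses the limma estimates ± SE, from -1.79 for SCO0168 to 1.21 for SCO4678.

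Limma called 0 of 7103 genes at an adjusted p under 0.05, and 186 genes had an unadjusted p under 0.05 (64 higher and 122 lower) where chance alone gives 355. The same direction on all 4 arrays was seen for 209 genes that were higher (2.94%) and 250 that were lower (3.52%), against 6.25% each for independent coin flips. Ratios from opposite dye orientations correlated below 0, so the arrays are not such flips, and the lower shares do not speak against strain differences. The 95% interval of 6763 genes (95.2%) lay within a 2-fold change in either direction. Such an interval bounds the measured ratio, and not the transcript where signal arises without a target. By mean amplitude only 975 of the 7103 genes (13.7%) lay above the 95th percentile of SCP1 probes. The interval of the replaced gene pfkA2 also lay within 2-fold (-0.52 to 0.31). Of the 125 genes tested that the rule for named genes picked, 96 moved by over 1.5 times or turned their sign with 1 array left out, and 40 turned it. The rule also took in genes with estimates near 0, such as SCO5429 (-0.0016), whose sign turns with small moves. The share over all genes was not computed. Without replicate 4 the count of calls was 182 of 7272 genes (25 higher, 157 lower), in a fit where replicate 2 is the only array of its orientation and its own deviations enter no residual, and those genes had a median absolute log2 ratio of 2.41 on replicate 2 and 0.35 on the others. On replicate 4, which shares that orientation, the 178 of them that it measured had a median of 0.24 in the direction of the call, against 2.41 on replicate 2.

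Whether the antibiotic clusters were transcribed more in the mutant is the question the title raises. For the blue antibiotic actinorhodin, 17 of 22 genes were lower and 5 higher in the RNA labelled mutant. The median of their limma estimates was -0.10, and the medians on the single arrays lay between -0.09 and -0.017. Its pathway activator actII-ORF4 (SCO5085) was at -0.071 ± 0.15, the largest ratio was 0.79 ± 0.26 for SCO5071, and SCO5091 was at -0.43 ± 0.15 and SCO5075 at -0.31 ± 0.18. Leaving out replicate 1 took SCO5071 to 0.40 and SCO5075 to -0.11. The cluster of the red antibiotic undecylprodigiosin had 12 genes higher and 9 lower (median 0.032), with its activators redD (SCO5877) at -0.18 ± 0.17 and redZ (SCO5881) at -0.14 ± 0.17. Of the 36 genes for the calcium-dependent antibiotic 20 were higher and 16 lower (median 0.022), with the activator cdaR (SCO3217) at 0.33 ± 0.27, SCO3239 at -0.46 ± 0.25 (-0.090 without replicate 2) and SCO3222 at 0.38 ± 0.18 (0.20 without replicate 2). The coelimycin cluster had 8 genes higher and 12 lower (median -0.050), with cpkO (SCO6280) at -0.017 ± 0.17 and SCO6282 at -0.27 ± 0.28 (0.16 without replicate 2). The sign of every activator turned with 1 array left out: without replicate 2 SCO3217 was at -0.067, SCO5877 at 0.0030, SCO5085 at 0.0044 and SCO6280 at 0.13, without replicate 3 SCO6280 was at 0.067, and without replicate 1 SCO5881 was at 0.027. With median centring SCO3217 was at 0.64 and SCO6280 at 0.16.

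By limma 0 members of these 4 clusters passed over all genes or when adjusted over the list alone. The 2 with an unadjusted p under 0.05 were SCO5071 and SCO5091. Above the 95th percentile of SCP1 probes lay 3 of 22 actinorhodin and 2 of 21 undecylprodigiosin genes. For the calcium-dependent antibiotic 2 of 36 genes lay above it, and for coelimycin 1 of 20. The other members were not told apart from signal without a target by this measure. For them the missing calls do not exclude a change of the transcript. Camera with a preset correlation of 0.01 called none of the 4 as a list (adjusted p = 0.184 for actinorhodin, 0.559 for undecylprodigiosin and for the calcium-dependent antibiotic, and 0.847 for coelimycin). The median of the actinorhodin cluster lay at percentile 1.33 among 10000 random lists matched on amplitude, and it stayed below 0 in every alternative, from -0.14 to -0.036. Such random lists ignore the correlation of genes within a cluster. By camera with an estimated correlation actinorhodin had an adjusted p = 0.685. The medians of the other clusters had both signs over the alternatives, and with median centring in place of loess the calcium-dependent antibiotic cluster rose by a median of 0.20 (adjusted p = 0.00307 by camera with preset correlation). That call too was lost with an estimated correlation (adjusted p = 0.606 by camera with median centring). Camera with an estimated correlation has few degrees of freedom here, so its adjusted p-values do not exclude a shift of either cluster.

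In central carbon metabolism 16 of 21 genes of the citrate cycle and its anaplerotic reactions had ratios below 0 in the RNA labelled mutant, with a median of -0.16. Phosphoenolpyruvate carboxylase (ppc, SCO3127) was at -0.44 ± 0.29, succinate dehydrogenase (sdhA, SCO4856) at -0.38 ± 0.18, SCO4827 at -0.34 ± 0.19 and succinyl-CoA synthetase (sucC, SCO4808) at -0.31 ± 0.19. All 4 leaned on single arrays: without replicate 4 SCO3127 was at -0.054, SCO4856 at -0.20 and SCO4827 at -0.14, and without replicate 1 SCO4808 was at -0.086. Glycolysis without pfkA2 had 6 members higher and 9 lower (median -0.041), among them the pyruvate kinase gene SCO2014 at -0.54 ± 0.26, SCO4209 at -0.28 ± 0.16 and the glyceraldehyde-3-phosphate dehydrogenase gene gap (SCO1947) at -0.24 ± 0.18. Without replicate 2 SCO2014 was at -0.16 and SCO1947 at -0.031, and without replicate 4 SCO4209 was at -0.14. The other phosphofructokinase genes, pfkA1 (SCO2119) and pfkA3 (SCO1214), were at 0.24 ± 0.14 and -0.15 ± 0.24, and without replicate 2 SCO1214 was at 0.17. With median centring SCO2119 was at 0.031, SCO1214 at -0.36, SCO6661 at 0.53 and SCO1937 at -0.011. In the pentose phosphate pathway 8 members were higher and 5 lower (median 0.050), with the glucose-6-phosphate dehydrogenase genes zwf at 0.26 ± 0.20 (SCO6661) and 0.10 ± 0.14 (SCO1937), SCO6661 at 0.0058 and SCO1937 at 0.048 without replicate 1, opcA (SCO1938) at 0.24 ± 0.14, the transketolase gene tkt (SCO1935) at 0.22 ± 0.16 (0.082 without replicate 2) and SCO0579 at -0.26 ± 0.14.

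The citrate cycle list fell by the camera test with preset correlation (adjusted p = 0.0476), and its adjusted p = 0.685 with an estimated correlation, with medians of -0.57, 0.20, -0.15 and -0.090 on replicates 1 to 4. Its median was -0.086 without replicate 1 (adjusted p = 0.433) and -0.13 without replicate 4 (adjusted p = 0.682), and relative to all genes it stayed below 0 in every alternative. Camera did not call glycolysis (adjusted p = 0.606) or the pentose phosphate pathway (adjusted p = 0.559). The medians of both lists took either sign over the alternatives, and with median centring glycolysis fell by camera with preset correlation (median -0.19, adjusted p = 0.0159) but not with an estimated correlation (adjusted p = 0.606). By limma 0 members of these 3 lists passed over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05.

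For ribosomal proteins and the respiratory chain most genes had ratios below 0 in the RNA labelled mutant, and the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.685 with an estimated correlation). Of 30 ribosomal protein genes 24 were lower and 6 higher (median -0.20), for example rplI (SCO3909, -0.61 ± 0.24), rplA (SCO4649, -0.44 ± 0.15) and rpsJ (SCO4701, -0.33 ± 0.20), and the probe of rplO, at background, counts among the 6. Without replicate 2 SCO3909 was at -0.27 and SCO4701 at -0.10. Of 29 genes for the respiratory chain and the ATP synthase 22 were lower and 7 higher (median -0.15), with atpB (SCO5367) at -0.90 ± 0.30, the cytochrome gene qcrC (SCO2150) at -0.47 ± 0.21, SCO4562 of the NADH dehydrogenase at -0.44 ± 0.19 and SCO4571 of the same complex at 0.49 ± 0.23. On replicates 1 to 4 atpB read -1.97, -0.94, -1.54 and 0.87. Leaving out replicate 2 took SCO5367 to -0.44 and SCO4571 to 0.22, and leaving out replicate 1 took SCO2150 to -0.28 and SCO4562 to -0.22. The 4 genes that make the compatible solutes ectoine and hydroxyectoine were all higher (median 0.21), with ectB (SCO1865) at 0.37 ± 0.15, ectA (SCO1864) at 0.25 ± 0.15, SCO1866 at 0.18 ± 0.22 and thpD (SCO1867) at 0.15 ± 0.21. Without replicate 4 SCO1864 was at 0.16, and without replicate 1 SCO1866 was at -0.045 and SCO1867 at -0.067. Above the 95th percentile of SCP1 probes lay 16 of the ribosomal, 9 of the respiratory and 0 of the ectoine genes.

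By camera with preset correlation the ribosomal and respiratory lists fell (adjusted p = 0.0194 for each) and the ectoine list rose (adjusted p = 0.0377). None of these calls, nor that of the citrate cycle, held with an estimated correlation (adjusted p = 0.685 with an estimated correlation for each list). That version of camera rests on 2 residual degrees of freedom, so the loss does not tell correlated genes from a lack of power. Fry called 0 of the 23 lists, with 1, ribosomal proteins, at an unadjusted p under 0.05. The array medians on replicates 1 to 4 were -0.33, 0.017, -0.19 and -0.072 for ribosomal proteins, -0.50, -0.10, -0.25 and -0.14 for the respiratory chain, and 0.59, 0.098, 0.28 and 0.094 for ectoine. Without replicate 1 the medians were -0.15, -0.13 and 0.10 in that order (adjusted p = 0.265, 0.198 and 0.407), and without replicate 4 they were -0.10, -0.077 and 0.27 (adjusted p = 0.331 for each). Leaving out replicate 2 also ended the ectoine call, at a median of 0.34 and an adjusted p = 0.0574. By limma 0 members passed over all genes or when adjusted over the list alone, while 3 ribosomal, 3 respiratory and 1 ectoine gene had an unadjusted p under 0.05, rplO with its probe at background among them.

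The remaining lists were not called by camera, and by limma 0 of their members passed over all genes or adjusted over the list alone. Those with an unadjusted p under 0.05 were chpE, glnR, desA and SCO0216. Among the genes for the surface of aerial hyphae (chaplins, rodlins and SapB) 10 of 15 were higher (median 0.029, adjusted p = 0.114), led by chpE (SCO1800) at 1.12 ± 0.30, which was at -0.68 on replicate 1, and chpG (SCO2705) at 0.37 ± 0.19. Without replicate 3 SCO1800 was at 0.72, and without replicate 1 SCO2705 was at 0.15. The gas vesicle clusters had 7 genes higher and 5 lower (median 0.018, adjusted p = 0.347), with SCO0651 at -0.54 ± 0.35 (0.024 without replicate 2) and SCO0650 at 0.32 ± 0.14. In the whiE cluster of the grey spore pigment 6 of 8 genes were lower (median -0.14, adjusted p = 0.216), with SCO5317 at -0.31 ± 0.21 (-0.034 without replicate 2). Heat shock chaperones had 5 of 7 genes lower (median -0.14, adjusted p = 0.184), with groES (SCO4761) at -0.34 ± 0.14 and dnaJ (SCO3669) at -0.24 ± 0.16 (-0.12 without replicate 2). For oxidative stress and thiol redox 5 genes were higher and 4 lower, and the median of 0.041 had the opposite sign to the mean of -0.043 and to the test (adjusted p = 0.807), with the redox sigma factor gene sigR (SCO5216) at -0.33 ± 0.17 (-0.17 without replicate 1).

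The phosphate starvation genes had 5 members higher and 3 lower (median 0.042, adjusted p = 0.320), led by the phosphate transporter genes pstB (SCO4139, 0.50 ± 0.22) and pstC (SCO4141, 0.49 ± 0.27). Without replicate 1 SCO4139 was at 0.21, and without replicate 2 SCO4141 was at 0.077. Nitrogen assimilation had 2 higher and 5 lower (median -0.039, adjusted p = 0.559), with its regulator glnR (SCO4159) at -0.41 ± 0.17 (-0.24 without replicate 2) and glnA (SCO2198) at -0.11 ± 0.14. Fatty acid synthesis had 2 of 4 genes higher (median 0.12, adjusted p = 0.320), with SCO2388 at 0.39 ± 0.23 (0.071 without replicate 2). Siderophore genes had 5 higher and 7 lower (median -0.080, adjusted p = 0.394), with SCO0496 at -0.44 ± 0.20 (-0.21 without replicate 2) and desA (SCO2782) at 0.41 ± 0.16. Hopanoid genes had 4 higher and 7 lower (median -0.023, adjusted p = 0.856), and all 4 carotenoid genes tested were lower (median -0.11, adjusted p = 0.320), with SCO0187 at -0.38 ± 0.24 (-0.047 without replicate 2). The carotenoid list had medians of -0.33, -0.33, 0.20 and 0.079 on replicates 1 to 4. Without replicate 1 SCO0189 was at 0.0027 and SCO0185 at 0.12. The respiratory nitrate reductases had 5 genes on each side, a median of 0.0044 against a mean of -0.14 and a negative test direction (adjusted p = 0.674), with SCO0216 at -1.16 ± 0.43 and narI (SCO6532) at -0.45 ± 0.30. Leaving out replicate 2 took SCO0216 to -0.43 and SCO6532 to 0.026. With median centring in place of loess the chaplin, gas vesicle and phosphate starvation lists rose by camera with preset correlation (adjusted p = 0.0272, 0.0272 and 0.0159), and the chaplin list also rose with loess by block (adjusted p = 0.0383). None of these calls held with an estimated correlation (adjusted p = 0.606 by camera for each list with median centring, and 0.513 for the chaplins with loess by block).

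**Figure D3:**
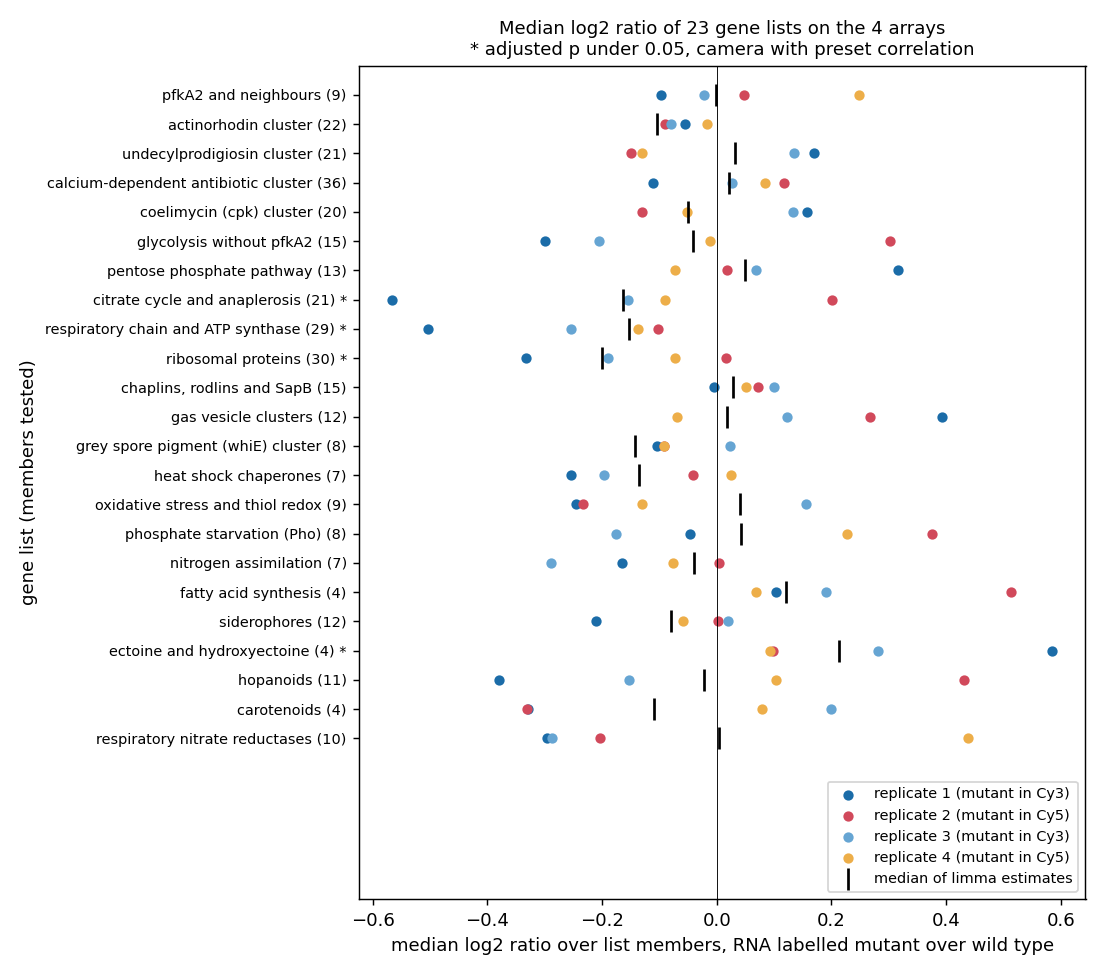
Median log2 ratio of the RNA labelled mutant over wild type for 23 gene lists (members tested in brackets), as coloured points for the 4 arrays and a black bar for the median of the limma estimates. Asterisks mark the 4 lists that camera called with a preset correlation (medians -0.16, -0.15, -0.20 and 0.21), none of which was called with an estimated correlation (adjusted p = 0.685 for each).

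Along the chromosome, neighbouring genes were compared in 782 windows of 20 gene numbers that overlap by 10, a scan added after the gene values were seen. The window from SCO0190 to SCO0209 had the lowest median, -0.35 with 14 of 16 genes lower, among them SCO0198 (-0.83 ± 0.17), the alcohol dehydrogenase gene adhP (SCO0199, -0.85 ± 0.29) and SCO0206. Its medians were 0.0079 and 0.077 on replicates 1 and 3, which carried the RNA labelled mutant in Cy3, and -0.58 and -0.60 on replicates 2 and 4. The window from SCO4670 to SCO4689 had the highest median, 0.26 with 18 of 20 genes higher, among them SCO4678, SCO4675 (0.66 ± 0.21), SCO4680 and the glutamate dehydrogenase gene gdhA (SCO4683, 0.23 ± 0.23). Its medians were 0.72, 0.22, 0.16 and 0.19 on replicates 1 to 4. In 1000 shuffles of the genes the most extreme window had a 95th percentile of 0.23, and 5 real windows lay beyond it, 2 lower and 3 higher. Because windows overlap, these were 3 separate regions, the third of them from SCO0350 to SCO0369 at 0.24. Without replicate 2 the lowest window had a median of -0.19, and without replicate 1 the highest had a median of 0.16. Both are smaller in size than the shuffle percentile of 0.23, which was computed for the fit to all 4 arrays alone. Without replicate 2 SCO0199 was at -0.45 and SCO4683 at -0.090.

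**Figure D4:**
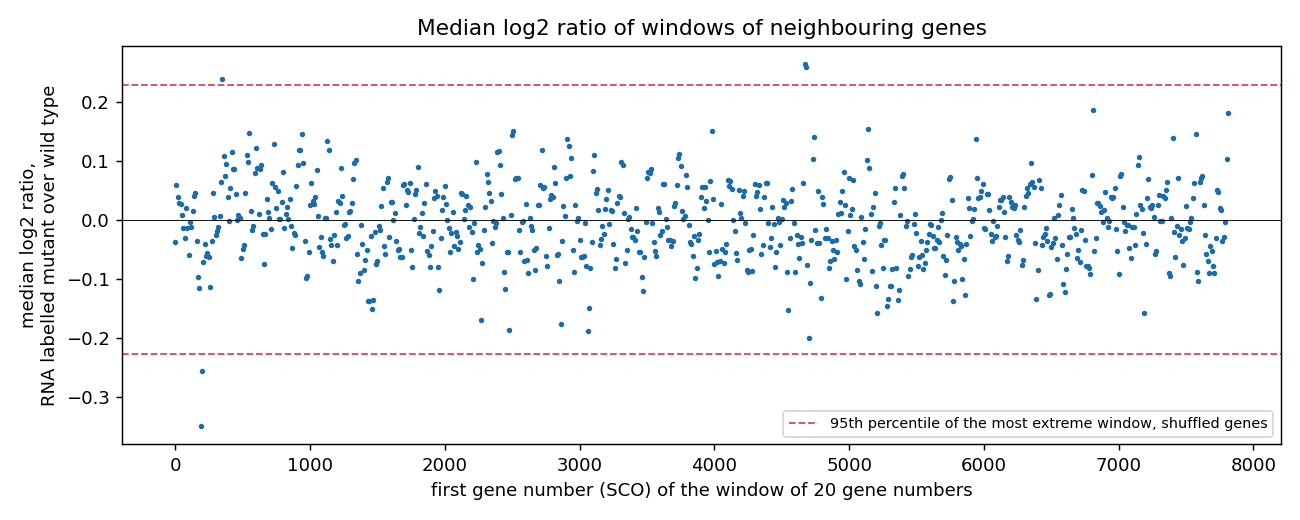
Median log2 ratio of the RNA labelled mutant over wild type in windows of 20 gene numbers, against the first gene number of the window. Dashed lines mark 0.23 on either side of 0, the 95th percentile of the most extreme window in 1000 shuffles, and 5 of 782 windows lie beyond them.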

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

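The tests for signal without a target on the pfkA2 probe and for the position of that probe were chosen only after the results were seen. Of 152 values tested over the 4 arrays, 4 had an array apart by Dixon's criterion at the 95% level, where chance gives 7.6.

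For ectA (SCO1864) replicate 2 lay apart at -0.045, against 0.30 to 0.37 on the other arrays (gap over range 0.834). For narI (SCO6532) replicate 2 lay apart at -1.76, with the others at -0.017, -0.090 and 0.10 (gap over range 0.895). For the median of the whiE cluster replicate 3 lay apart at 0.024 (gap over range 0.907). For the median of the respiratory nitrate reductases replicate 4 lay apart at 0.44, against -0.30, -0.20 and -0.29 (gap over range 0.875). The SCP1 probes, for which neither strain carries a target, gave a median amplitude of 1.44 to 4.01 times that of the negative controls over the 8 channels.

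Across genes, ratios of mutant over wild type from arrays of opposite dye orientation correlated at -0.39 on average (95% bootstrap interval -0.412 to -0.374). The brightest 1776 genes gave -0.487 (-0.524 to -0.453), so dim spots were not the source. SCP1 probes gave -0.36 (-0.435 to -0.281). An exchange of the strain labels on both arrays of 1 orientation cannot produce that value, since neither strain carries their target. Such an exchange is therefore not the only source of negative correlations on these arrays. Whether it adds to the value over genes cannot be told from probes without a target. A bias of each probe towards 1 dye is consistent with the SCP1 value of -0.36, and it may account for the pattern. In a joint fit of SCP1 probes and genes the log2 ratios of mutant over wild type had an SD of 0.19 over SCP1 probes and 0.22 over chromosomal genes, and 3 of 264 SCP1 probes (1.14%) against 183 of 7103 genes (2.58%) had an unadjusted p under 0.05 (Fisher's exact test, two-sided p = 0.164).

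The pfkA2 probe showed no loss of signal that passed the test in the RNA labelled mutant, at -0.11 ± 0.17 on the log2 scale (95% interval -0.52 to 0.31). With the RNA labelled wild type its amplitude exceeded the 95th percentile of SCP1 probes on 0 of 4 arrays, so nonspecific signal on the probe could account for the missing difference. Whether the probe lies outside the deleted part cannot be told apart from this, because the gene has 1 probe and its position is not given. An exchange of labels between the strains was not tested on this gene.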

How the results depend on the processing

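The offset of 50, flag A spots alone, the SCP1 filter, the array weights and camera with an estimated correlation under other normalisations were added after the data were seen. Signal close to that of SCP1 probes limits most genes. The estimate for pfkA2 ran from -0.28 to 0.073 over 17 alternatives and passed in none. The uncentred deposited ratios shifted the median of all genes by 0.21, and ranges are relative to it. Over all alternatives the medians ran from -0.26 to -0.047 for the citrate cycle, -0.24 to -0.069 for the respiratory chain, -0.43 to -0.10 for ribosomal proteins and 0.10 to 0.38 for ectoine. No called result reversed, and in 19 cases a single gene or list that had not passed did so under an alternative. Window medians kept their sign in 17 alternatives (-0.39 to -0.19 and 0.16 to 0.33). No background correction was applied in the main fit, so that setting, listed beforehand, was no separate alternative. Normexp without offset, also listed, was not run, since the files give no background. The mutant extract as a random block was fitted by restricted likelihood. Each array holds both strains, so every ratio is already a pair within its array.

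Calls of single genes numbered 1 with loess by block (SCO6627, adjusted p = 0.0272), 2 with flag A spots (SCO6627, adjusted p = 0.0236, and SCO0206, adjusted p = 0.0392; 5257 genes tested), 2 among the 502 genes above the SCP1 percentile in at least 1 channel on all 4 arrays (stricter than by mean amplitude; SCO7657, adjusted p = 0.00526, and SCO3041, adjusted p = 0.0338) and 0 to 182 with 1 replicate left out, all by limma. An adjusted p under 0.1, or a 2-fold change on top, left 0.

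With median centring, camera called 1 antibiotic list (calcium-dependent antibiotic), 2 central carbon lists (glycolysis added) and 5 other lists. The uncentred ratios gave 1, 2 and 5, with medians of 0.42 for the calcium-dependent antibiotic and 0.045 for glycolysis, the latter below the shift of all genes. With an estimated correlation 0 lists were called under median centring, loess by block and the uncentred ratios (lowest adjusted p = 0.606, 0.513 and 0.896). Ectoine lost its call in both normalisations without loess (0.151, adjusted p = 0.220, and 0.387, adjusted p = 0.302).

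With flag E spots kept, 0 central carbon and 0 other lists were called, at -0.188 for the citrate cycle, -0.155 for the respiratory chain, -0.132 for ribosomal proteins and 0.198 for ectoine (adjusted p = 0.0827, 0.0502, 0.0621 and 0.0621). The citrate cycle, and with it the central carbon count of 0, was lost with the correlation at 0.5 (-0.212, adjusted p = 0.109), an offset of 50 (-0.158, 0.0524), flag A spots (-0.0472, 0.623), array quality weights (-0.164, 0.0564) and the SCP1 filter (count 0, too few members). Under that filter the other lists numbered 1, and the respiratory chain was at -0.0685 (adjusted p = 0.847).

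With camera's estimated correlation and with fry, 0 lists were called in either group, at unchanged medians of -0.164, -0.154, -0.20 and 0.213. With 1 replicate left out the counts were 0 to 1 for central carbon and 0 to 3 for the other lists, and the medians ran from -0.255 to -0.0862 for the citrate cycle, -0.162 to -0.0769 for the respiratory chain, -0.222 to -0.101 for ribosomal proteins and 0.101 to 0.383 for ectoine. The cause of these changes was not tested, except that filters tested fewer genes and that fits without a replicate had fewer arrays. Camera with an estimated correlation also had fewer degrees of freedom than camera with the preset one.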

Other observations

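The tests on gene windows were chosen only after the results were seen, except that of spot position.

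The genes near SCO0200 belong to a region known for its control by a regulator pair that responds to oxygen and stress. Within the window from SCO0190 to SCO0209 the ratio of SCO0206 was lowest, -1.50 ± 0.17. The pyruvate formate-lyase activating gene pflA (SCO0205, annotated as a pseudogene) was at -0.66 ± 0.41, with 1.25 on replicate 1 and -3.60 on replicate 2, and 0.016 without the latter. SCO0197 was at -0.41 ± 0.18 (-0.20 without replicate 2) and SCO0204 at -0.53 ± 0.25 (-0.17 without replicate 4), while SCO0203 was at -0.029 ± 0.17 and the pyruvate phosphate dikinase gene ppdK (SCO0208) at -0.039 ± 0.16. None of these genes passed limma's test with Benjamini-Hochberg adjustment. In the high window SCO4679 was at 0.50 ± 0.19, SCO4687 at 0.55 ± 0.22 and SCO4689 at 0.62 ± 0.29, and SCO4671 (-0.24 ± 0.20) and SCO4686 (-0.36 ± 0.18) were its lower genes. Without replicate 1 SCO4679 was at 0.27, SCO4687 at 0.24 and SCO4689 at 0.17, and without replicate 2 SCO4671 was at 0.017 and SCO4686 at -0.16.

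In 3 regions genes of neighbouring numbers had a more extreme median ratio than shuffled genes, most of all from SCO0190 to SCO0209 at a median of -0.35. In 0 of 1000 shuffles of the genes was a window as extreme, so chance placement is excluded for the value over 4 arrays. Without replicate 2 the window's median was -0.19, and no shuffles were run for that fit, so chance placement is not excluded there. The 480 spots within 2 rows and columns of the window's spots had a median of -0.061, which is 0.174 times that of the window (0.128 to 0.227). The place of the spots at that distance therefore does not account for most of the window's median. The surrounding median was itself below that of all genes (-0.0045), so a small part may be shared with place. The window was low only on the 2 arrays with the RNA labelled mutant in Cy5. A probe bias towards 1 dye that is the same on all arrays cancels in the median of -0.35, since both orientations are balanced and fitted with a dye term. A bias of unequal size would not cancel in full. Over SCP1 probes the ratios correlated at 0.136 between replicates 2 and 4 and at 0.416 between replicates 1 and 3, so an equal bias was not shown. Whether an unequal bias adds to the window's median was not tested. Co-regulation of neighbouring genes that differed between the strains, or between the 2 mutant and 3 wild-type extracts, may explain the pattern and remains untested.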
